A study of Caenorhabditis elegans with 12 samples.

How the data were processed

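Transcript levels of whole Caenorhabditis elegans were measured in 12 RNA-seq libraries, 3 in each of 4 groups. The groups were wild type (N2) and the mutant glp-1(e2141), each at day 1 (D1) and day 6 (D6) of adulthood. Per the labels' protocols, synchronized larvae grew on plates with OP50 bacteria at 25 °C to D1, and the D6 animals were then held at a lower temperature. RNA was extracted with TRIzol, libraries were made with the NEBNext Ultra RNA kit, and sequencing was on an Illumina NovaSeq instrument, per the labels and the series' design text. The design text gives 20 °C for the time after D1, while the labels of the D6 samples give 20 °C for replicate 1, 21 °C for replicate 2 and 22 °C for replicate 3 in both genotypes. Age is therefore joined to a temperature shift in both genotypes. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

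Each deposited file holds 1 value per gene in FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library), as computed by the authors, per the file headers. The submitters' processing notes name HISAT2 2.0.4, DESeq2 1.6.3 and the genome build WBcel235. The program that computed FPKM, the annotation release and any filter are not given in the sources used here. All files list the same 20257 genes. Of these names 18237 matched a gene symbol of the WBcel235 annotation used for coordinates, and 11 names had been changed to spreadsheet dates and were kept as written. Blank lines at the end of files were dropped. No pair of files held identical values. Whether fragments were counted by strand is not given in the sources used here, so overlapping genes on opposite strands, and near-identical copies such as act-1 and act-3, vit-3, vit-4 and vit-5, the msp genes and some tubulin genes, are uncertain one by one.

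FPKM divides by gene length and by each library's own total, so a gene's value is its share of the RNA sequenced. Removal of a tissue rich in RNA raises the shares of the others without any change within cells. Whole fragment counts cannot be recovered exactly from FPKM. An approximate depth came from the smallest steps between low values of 12687 genes with 1 annotated transcript, which gave 17.2 M to 19.8 M fragments (M for 10 to the power of 6) per library. All 12 libraries were thus of similar estimated depth. Intervals for counting error were not computed, because they need the counts.

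The design fixed before the data were examined assumed counts and a quasi-likelihood count test. The values are FPKM, for which a count test is unsuited, so the test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend of the variance on the mean and robust empirical Bayes moderation. Fold changes are on this log2(FPKM + 1) scale, which understates the change of genes of low level. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 13614 genes tested and 6643 left out. FPKM were used as deposited, with no further scaling. These 3 choices were made after the values had been seen, and scaling factors and medians of gene lists under several scalings had been looked at by then. One mean per group was fitted over all 12 libraries with 8 residual degrees of freedom. The contrasts were glp-1 against wild type at each age, D6 against D1 in each genotype, and the interaction, the change with age in glp-1 minus that in wild type. Adjusted p is the Benjamini-Hochberg value over the genes tested, and a gene was called at adjusted p under 0.05. All p-values are two-sided.

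On simulated values for the 13614 genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, the test for glp-1 against wild type at D1 recovered 68.7%, 92.5% and 97.0% of them. At D6 it recovered 64.2%, 92.5% and 100%. For age in wild type the shares were 61.2%, 85.1% and 100%, for age in glp-1 62.7%, 86.6% and 100%, and for the interaction 31.3%, 67.2% and 98.5%. False calls made up 3.37%, 3.39%, 6.29%, 7.78% and 4.38% of the calls in these 5 comparisons, in that order, so those for age lay slightly over the nominal 5%. These shares rest on few calls (6, 6, 11, 14 and 6). The changed genes were drawn only from those with a mean over 2 on the log2(FPKM + 1) scale, so recovery at lower levels was not measured. The simulated noise was independent between genes. Far fewer genes were changed in the simulation than were called in the data. The Benjamini-Hochberg cut depends on the share of genes changed, so recovery and false calls in the data can differ from these values.

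Before the data were examined, 30 gene lists with 665 entries were fixed. Of the entries 640 were found by symbol, 7 by sequence name and 18 were not found under either, which left 29 lists to test. The lists were tested with camera (limma) at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 29 lists, again with a correlation estimated per list, and with fry. A list's members are described as rose, fell or not passing by the test over all genes. Lists overlap in a few genes, such as sip-1, which is in the lists of DAF-16 targets and of chaperones.

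The genes named follow a rule fixed beforehand. It takes every intermediate filament gene and the glp-1 gene, then the 5 called genes with the largest rise and the 5 with the largest fall in each comparison among genes with a symbol whose replicates did not overlap, then up to 4 called members of each list with the largest change. The rule's minimum of 10 counts became a mean of at least 1 FPKM in each group, and its minimum of 10 CPM became a mean of 10 FPKM. Coordinates are those of WBcel235, counted from 1.

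Alternatives fixed beforehand were median ratio scaling, rescaling to the same total, scaling to the muscle and neuron lists, no filter, a mean of at least 5 FPKM (in place of a mean count), fits of only the groups compared, 2 rules on size, a block for the replicate number and leaving out each library. Pseudocounts of 0.1 and 5, trimmed mean scaling and the representation of glp-1 at D6 by replicate 2 alone were added after the data had been seen. So was the set of 68 germline genes, the members of the germline, oocyte and cell cycle lists whose mean in glp-1 at D1 lay below 3% of that in wild type. Tests with DESeq2 and with limma-voom were planned and not run, since both need counts. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.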

Results

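The data are transcript levels of whole worms at 2 adult ages and in 2 genotypes, with 3 libraries in each of the 4 groups. One genotype was wild type and the other glp-1(e2141), a temperature-sensitive allele of a Notch receptor that germline stem cells need, so that animals raised at 25 °C have almost no germline. The series is about intermediate filaments, the rope-like proteins of the cytoskeleton and nuclear lamina, and lifespan. Animals without a germline live longer, and the design asks what differs between the genotypes at D1 and at D6, and what changes between these ages in each. Libraries held an estimated 17.2 M to 19.8 M fragments. Between 11100 and 12113 genes reached 1 FPKM. The 20 most abundant genes took 7.46% to 9.16% of all FPKM in the wild-type libraries and 17% to 19.1% in the glp-1 libraries. Rank correlations between libraries of one group lay between 0.967 and 0.978, those between ages of one genotype between 0.933 and 0.948, and those between genotypes between 0.738 and 0.798.

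The glp-1 gene (WBGene00001609, chromosome III, 9092241 to 9099698, plus strand) had a mean of 66.8 ± 2.16 FPKM (SD, n = 3) in wild type at D1 and 3.32 ± 0.0981 in glp-1. At D6 the means were 97.9 ± 1.24 and 6.09 ± 0.626. The log2 fold change of glp-1 against wild type was -3.97 (SE 0.08) at D1 and -3.81 (SE 0.08) at D6. All 6 mutant libraries lay below all 6 wild-type libraries. The e2141 allele changes the protein and was not read from these values.

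Intermediate filament genes were mostly higher in glp-1 than in wild type, and mostly lower at D6 than at D1. The gene ifb-1 (chromosome II, 5765618 to 5772084), the common partner of the epidermal filaments, had 84.2 ± 3.32 FPKM in wild type at D1, 29.5 ± 1.95 in wild type at D6, 226 ± 3.91 in glp-1 at D1 and 124 ± 6.41 in glp-1 at D6 (SD, n = 3). For mua-6 (also called ifa-2; chromosome X, 16262289 to 16265686), which joins the epidermis to muscle and cuticle, the means were 55.7 ± 8.48, 9.26 ± 0.551, 189 ± 1.39 and 63.0 ± 9.28 in the same order. The nuclear lamin lmn-1 (chromosome I, 8763041 to 8765631) went the other way, with 214 ± 3.59, 270 ± 4.36, 50.3 ± 1.45 and 50.1 ± 0.245 FPKM.

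**Figure D1:**
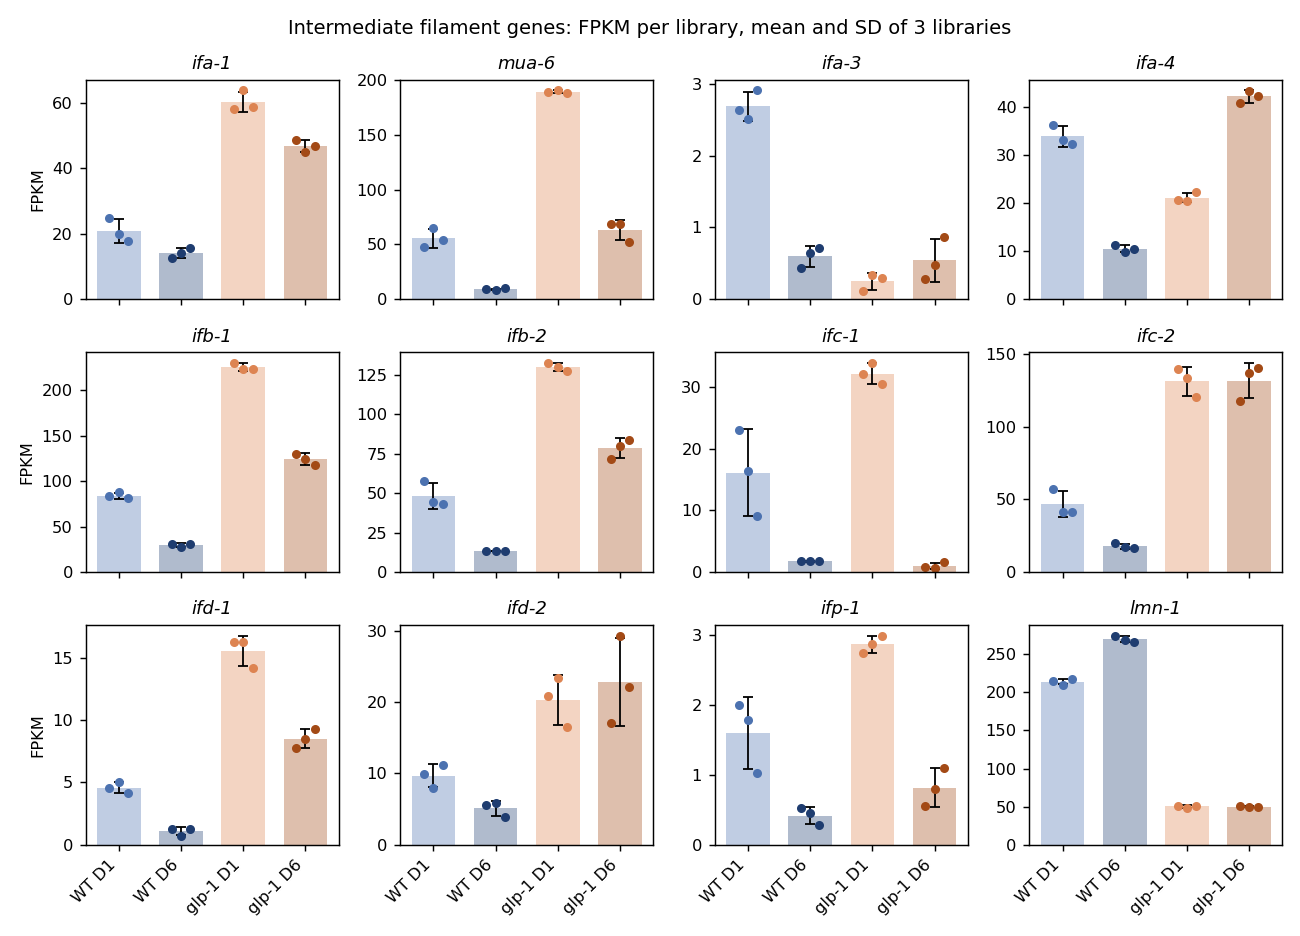
Levels of the 12 intermediate filament genes. Each panel shows 1 gene, with FPKM on a linear axis from 0 and the 4 groups side by side; points are libraries, bars are means and error bars are SD (n = 3). In the panel of mua-6 the mean falls from 55.7 to 9.26 FPKM in wild type and from 189 to 63.0 FPKM in glp-1.

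At D1, 9 of the 12 filament genes were higher in glp-1 and 3 were lower (median log2 fold change 1.23). The higher ones included mua-6 (1.76, SE 0.11), ifd-1 (1.57, SE 0.13), ifa-1 (1.49, SE 0.11), ifc-2 (1.48, SE 0.12), ifb-2 (1.43, SE 0.10), ifb-1 (1.41, SE 0.06), ifc-1 (1.04, SE 0.25), ifd-2 (0.99, SE 0.20) and ifp-1 (0.59, SE 0.17). The lower ones were lmn-1 (-2.07, SE 0.05), ifa-3 (-1.56, SE 0.15), which lay below 3 FPKM in every library, and ifa-4 (-0.65, SE 0.08). The list as a whole did not pass the camera test (adjusted p = 0.0548, and adjusted p = 0.295 with an estimated correlation). Levels scaled to the muscle and neuron lists gave 6 higher and 3 lower (median 0.40), and the list then passed camera (adjusted p = 0.0422).

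Germline transcripts made up the largest differences at D1. All 30 genes of germline stem cells and meiosis, all 25 of the cell cycle and replication, and all 11 tested sperm genes were lower in glp-1. The translational regulator gld-1 stood at 611 ± 5.10 FPKM in wild type and 0.620 ± 0.113 in glp-1, and the P granule gene pgl-1 had a log2 fold change of -7.87 (SE 0.29). Of 21 oocyte and eggshell genes 19 were lower, among them cpg-2 (-9.89, SE 0.52), cpg-1 (-9.77, SE 0.47) and pos-1 (-9.27, SE 0.42). The remaining pair, perm-2 and perm-4, which encode eggshell proteins and were picked for mention after their values were seen, were higher, with perm-2 at 1751 ± 98.9 FPKM in wild type and 2857 ± 289 in glp-1; scaled to the muscle and neuron lists, neither was called (0 higher, 19 lower). Of the mitotic genes, cyb-3 had -7.98 (SE 0.25) and mcm-4 -7.62 (SE 0.26). For these 4 lists camera adjusted p ran from 1.99e-08 to 0.00497, and adjusted p from 0.295 to 0.397 with an estimated correlation. By the rule for named genes, which asks for a mean of at least 1 FPKM in each group, the 5 largest falls were sip-1 (-10.41), cpg-2, cey-2 (-9.82), clec-87 (-9.66) and iff-1 (-9.49).

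Most somatic lists were higher in glp-1 at D1. Of 20 body wall muscle genes 16 were higher and 3 lower, with the troponin gene unc-27 at 1.69 (SE 0.12) and the paramyosin gene unc-15 at 1.52 (SE 0.17). Of 23 neuronal genes 21 were higher and 1 lower, with unc-25, for GABA synthesis, at 1.53 (SE 0.13). Of 14 intestinal genes 13 were higher, with the gut esterase ges-1 at 2.2 (SE 0.12). Of 16 basement membrane genes 10 were higher and none lower, with nid-1 at 2.08 (SE 0.09), and of 10 somatic gonad genes 8 were higher and 1 lower. All 6 vitellogenin genes, which encode yolk proteins, were higher, with vit-5 at 1.86 (SE 0.08). Of 14 adult cuticle genes 12 were higher, with col-119 at 1.61 (SE 0.14), while the collagen gene dpy-17 was lower at -5.33 (SE 0.21). Camera adjusted p for these 7 lists ran from 0.000104 to 0.0258, and adjusted p from 0.289 to 0.39 with an estimated correlation. Scaled to the muscle and neuron lists, which is no independent test of these 2, the other medians shrank to 0.84 for cuticle, 0.48 for intestine (8 higher), 0.43 for vitellogenins (3 higher), 0.0418 for basement membrane (6 higher, 4 lower) and 0.0103 for somatic gonad (3 higher, 4 lower). The somatic gonad call ended (camera adjusted p = 0.2), with inx-9 and inx-8 below 0. The pharynx list did not pass camera (6 of 10 higher, 1 lower; adjusted p = 0.0644), and had 1 higher and 2 lower in that scaling (median -0.0311).

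Stress and lipid genes were higher as well. Of 18 DAF-16 targets, genes raised by the FOXO factor of the insulin pathway, 16 were higher and 1 lower (camera adjusted p = 8.6e-05, and adjusted p = 0.289 with an estimated correlation). Among them were the metallothionein mtl-1 (5.33, SE 0.34), at 9.94 ± 5.77 FPKM in wild type and 396 ± 29.1 in glp-1, the ferritin ftn-1 (4.31, SE 0.35) and dod-3 (3.53, SE 0.23), while sip-1 was the lower one. Of 18 genes of fatty acid synthesis and desaturation 17 were higher, with the desaturases fat-5 (3.58, SE 0.10) and fat-6 (2.19, SE 0.06) (camera adjusted p = 3.87e-06, and adjusted p = 0.256 with an estimated correlation). Of 21 genes of lipases and beta-oxidation 12 were higher and 4 lower, led by lipl-2 (2.98, SE 0.19), a call that ended when scaled to the muscle and neuron lists (camera adjusted p = 0.148). Of 26 oxidative stress and detoxification genes 17 were higher and 7 lower, with sod-3 at 3.40 (SE 0.14), and of 31 innate immune effectors 21 were higher and 4 lower, with abf-2 at 3.68 (SE 0.16). Of 26 insulin-like peptide genes 18 were higher and 4 lower, with ins-31 at -3.10 (SE 0.22) and ins-7 at 1.71 (SE 0.18). Over the last 4 lists camera gave adjusted p from 0.00117 to 0.0258, and adjusted p from 0.256 to 0.39 with an estimated correlation. With the muscle and neuron scaling, medians shrank to 0.98 for DAF-16 targets, 0.50 for fatty acid synthesis (13 higher, 2 lower), 0.52 for immune effectors (16 higher, 8 lower), 0.38 for insulin-like peptides (7 higher, 4 lower), 0.0602 for lipases (8 higher, 10 lower) and 0.0216 for oxidative stress (12 higher, 12 lower). Further large rises were those of catp-3 (4.54), far-3 (4.25) and acox-2 (4.24).

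Proteasome and ribosomal genes were lower in glp-1 at D1. All 31 proteasome genes were lower (median -1.85), with rpn-1 at -2.19 (SE 0.05), and all 65 cytosolic ribosomal protein genes were lower (median -0.91), with rpl-22 at -1.30 (SE 0.08). Camera adjusted p was 1.99e-08 and 1.8e-07, and adjusted p = 0.233 and 0.426 with an estimated correlation. With the muscle and neuron scaling the medians were -2.68 and -1.76. Of 30 genes of oxidative phosphorylation 12 were higher and 6 lower (median 0.0801; camera adjusted p = 0.0849), and 3 higher and 26 lower in that scaling (median -0.76; adjusted p = 0.174). Several lists that did not pass camera held members in both directions. Of 28 chaperone genes 15 were lower and 10 higher, with the HSP90 gene daf-21 at -4.53 (SE 0.05) and the HSP70 gene hsp-1 at -3.21 (SE 0.06). Of 18 genes of hemidesmosomes and apical junctions 12 were higher and 5 lower, with the cadherin hmr-1 at -2.71 (SE 0.07) and mup-4 at 1.78 (SE 0.13). Of 24 autophagy and lysosome genes 11 were higher and 11 lower. Median and mean of the autophagy list (0.07 and -0.12) and of the germline-loss longevity regulators (0.22 and -0.15) differed in sign, and both medians fell below 0 when scaled to the muscle and neuron lists. Adjusted over the list alone, the counts were the same for 27 of the 29 lists.

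In all, limma called 12167 of 13614 genes at D1, 5624 higher and 6543 lower in glp-1, and 8769 of them differed at least 2-fold. The higher ones made up 46.2% of the calls, and 29.9% when levels were scaled to the muscle and neuron lists, which moved the median of all genes from -0.15 to -0.80. A difference in this comparison is one of shares of the sequenced RNA, between animals with and without a germline.

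At D6 the same contrast was asked again, in animals past the peak of egg laying. Of the 12 filament genes 8 were higher in glp-1, 1 was lower and 3 did not pass (median 1.93; camera adjusted p = 0.022, and adjusted p = 0.29 with an estimated correlation). The log2 fold changes were 2.82 (SE 0.12) for ifc-2, 2.63 (SE 0.11) for mua-6, 2.45 (SE 0.10) for ifb-2, 2.21 (SE 0.13) for ifd-1, 2.04 (SE 0.06) for ifb-1, 1.95 (SE 0.20) for ifd-2, 1.91 (SE 0.08) for ifa-4 and 1.66 (SE 0.11) for ifa-1. The lamin lmn-1 was lower (-2.41, SE 0.05). Values that did not pass were -0.49 (SE 0.25, adjusted p = 0.0863) for ifc-1, 0.35 (SE 0.17, adjusted p = 0.0589) for ifp-1 and -0.06 (SE 0.15, adjusted p = 0.709) for ifa-3. Without replicate 3 of glp-1 at D6 ifc-1 passed (-0.68, adjusted p = 0.029), and without replicate 1 ifp-1 did (0.46, adjusted p = 0.03). After scaling to the muscle and neuron lists, 8 were higher and 3 lower (median 0.76). The filament organizer ifo-1, in the junction list, had 3.06 (SE 0.13).

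Germline genes were again lower in glp-1 at D6. All 30 germline stem cell and meiosis genes, all 25 cell cycle genes and 19 of 21 oocyte genes were lower (camera adjusted p from 9.52e-09 to 0.000502, and adjusted p from 0.29 to 0.447 with an estimated correlation), with gld-1 at -7.09 (SE 0.34), cdk-1 at -7.04 (SE 0.36) and cpg-1 at -7.69 (SE 0.47). The 3 mutant libraries differed from each other in these genes. Over 68 germline, oocyte and cell cycle genes, replicate 1 held a median of 1.33% of the wild-type D6 level, replicate 3 held 0.774% and replicate 2 held 0.175%, while the D1 libraries held 0.126% to 0.200% of the wild-type D1 level. These genes were chosen for a mean below 3% of wild type in glp-1 at D1, so the low D1 shares are partly set by that choice. Of 11 sperm genes 5 were lower, 2 higher and 4 did not pass, with ssq-1 higher at 1.61 (SE 0.12); scaled to the muscle and neuron lists, 8 were lower and 1 higher.

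**Figure D2:**
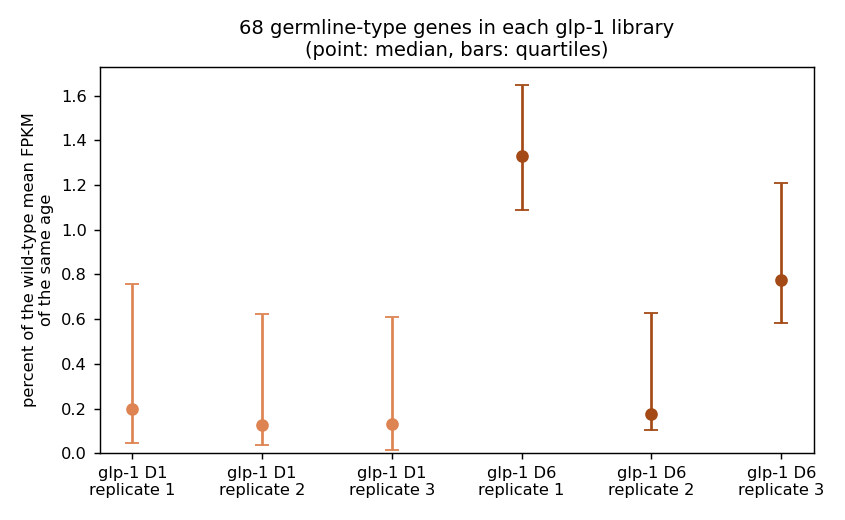
Germline-type transcripts in the 6 glp-1 libraries. The vertical axis is the percent of the wild-type mean FPKM of the same age, from 0. Points are medians over 68 genes and bars run from the lower to the upper quartile. The genes were chosen for a mean below 3% of wild type in glp-1 at D1. At D6 replicates 1 and 3 lie at 1.33% and 0.774%, and replicate 2 at 0.175%.

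Yolk, gut and lipid genes were higher in glp-1 at D6. All 6 vitellogenin genes were higher (median 2.83), with vit-3 at 157 ± 23.2 FPKM in wild type and 2099 ± 163 in glp-1. All 14 intestinal genes were higher, with ges-1 at 3.50 (SE 0.12) and the gut GATA factor elt-2 at 2.29 (SE 0.11). Of 18 fatty acid synthesis genes 17 were higher, with dgat-2 at 4.18 (SE 0.15), fat-5 at 4.09 (SE 0.10) and acs-22 at 3.24 (SE 0.08), and of 21 genes of lipases and beta-oxidation 14 were higher and 4 lower, with the peroxisomal genes acox-1 at 2.95 (SE 0.09) and dhs-28 at 2.74 (SE 0.10). Of 18 DAF-16 targets 17 were higher and 1 lower, with ftn-1 at 3.91 (SE 0.35). Of 31 immune effectors 25 were higher and none lower, with the lysozyme genes lys-2 at 3.59 (SE 0.33) and lys-7 at 3.38 (SE 0.15). For these 6 lists camera adjusted p ran from 7.31e-06 to 0.0161, and adjusted p from 0.29 to 0.379 with an estimated correlation.

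Other somatic lists were higher too. They were muscle (17 of 20 higher, 3 lower; tnt-2 at 2.55, SE 0.16), neurons (22 of 23 higher, 1 lower; egl-3 at 2.02, SE 0.13), pharynx (9 of 10; tni-4 at 1.91, SE 0.09), basement membrane (13 of 16; let-2 at 2.50, SE 0.14) and somatic gonad (7 of 10 higher, 1 lower; ipp-5 at 2.39, SE 0.13). Camera adjusted p for these 5 lists ran from 0.000179 to 0.0443, and adjusted p from 0.29 to 0.42 with an estimated correlation. Insulin-like peptide genes were higher in 18 of 26 and lower in 4 (camera adjusted p = 0.0472, and adjusted p = 0.29 with an estimated correlation), with daf-28 at 2.33 (SE 0.25). In the muscle and neuron scaling, medians shrank to 1.58 for vitellogenins, 1.21 for DAF-16 targets, 0.88 for fatty acid synthesis (13 higher, 2 lower), 0.67 for intestine (8 higher, 4 lower), 0.59 for basement membrane (12 higher, 4 lower), 0.58 for immune effectors (15 higher, 3 lower) and 0.25 for insulin-like peptides (8 higher, 6 lower). In that scaling the calls of pharynx and of lipases (adjusted p = 0.0607 each), somatic gonad (0.214) and insulin-like peptides (0.0512) ended. By the same rule the largest rises at D6 were those of the cytochrome P450 gene cyp-14A3 (5.54, SE 0.12), at 6.07 ± 0.573 FPKM in wild type and 328 ± 12.2 in glp-1, far-3 (5.41), col-183 (5.24), ugt-25 (4.98) and sdz-24 (4.46). The largest falls were sip-1 (-8.37), cey-2 (-7.89), clec-87 (-7.83), cav-1 (-7.77) and cpg-1.

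Respiratory chain, proteasome and ribosomal genes were lower in glp-1 at D6. Of 30 nuclear genes of oxidative phosphorylation 25 were lower and 5 higher (median -1.01; camera adjusted p = 0.00131, and adjusted p = 0.447 with an estimated correlation). The ATP synthase gene atp-2 stood at 1210 ± 53.2 FPKM in wild type and 356 ± 18 in glp-1, and asg-1 had -2.06 (SE 0.06). All 31 proteasome genes (median -1.91) and all 65 ribosomal protein genes (median -1.39) were lower, with rpn-11 at -2.53 (SE 0.05) and rps-21 at -1.96 (SE 0.12), camera adjusted p of 9.52e-09 and 7.63e-10, and adjusted p = 0.222 and 0.42 with an estimated correlation. With the muscle and neuron scaling the medians were -2.26 for oxidative phosphorylation (30 of 30 lower), -3.16 for the proteasome and -2.65 for ribosomal genes. Adult cuticle genes (5 higher, 1 lower, 8 not passing; adjusted p = 0.615) and chaperone genes (13 higher, 14 lower; adjusted p = 0.581) did not pass camera, and in that scaling had 2 higher and 7 lower (median -1.19) and 5 higher and 16 lower (median -1.44). As deposited, the cuticle list had a median of -0.37 while camera placed it upward, and the list of actins and tubulins had a median of 0.63 and a mean of -0.11. Adjusted over the list alone, the counts were the same for 28 of the 29 lists.

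In all 12221 genes were called at D6, 6045 higher and 6176 lower in glp-1, 9746 of them at least 2-fold. The higher ones made up 49.5% of the calls, and 34.3% after scaling to the muscle and neuron lists (median of all genes -0.03 and -0.87). Across genes, which are not independent replicates, the genotype differences at D1 and D6 correlated at r = 0.927. Genes higher at both ages numbered 5216 and lower at both 5811, against 2497 and 2968 for independent lists. Those higher at one age and lower at the other numbered 106 and 137.

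**Figure D3:**
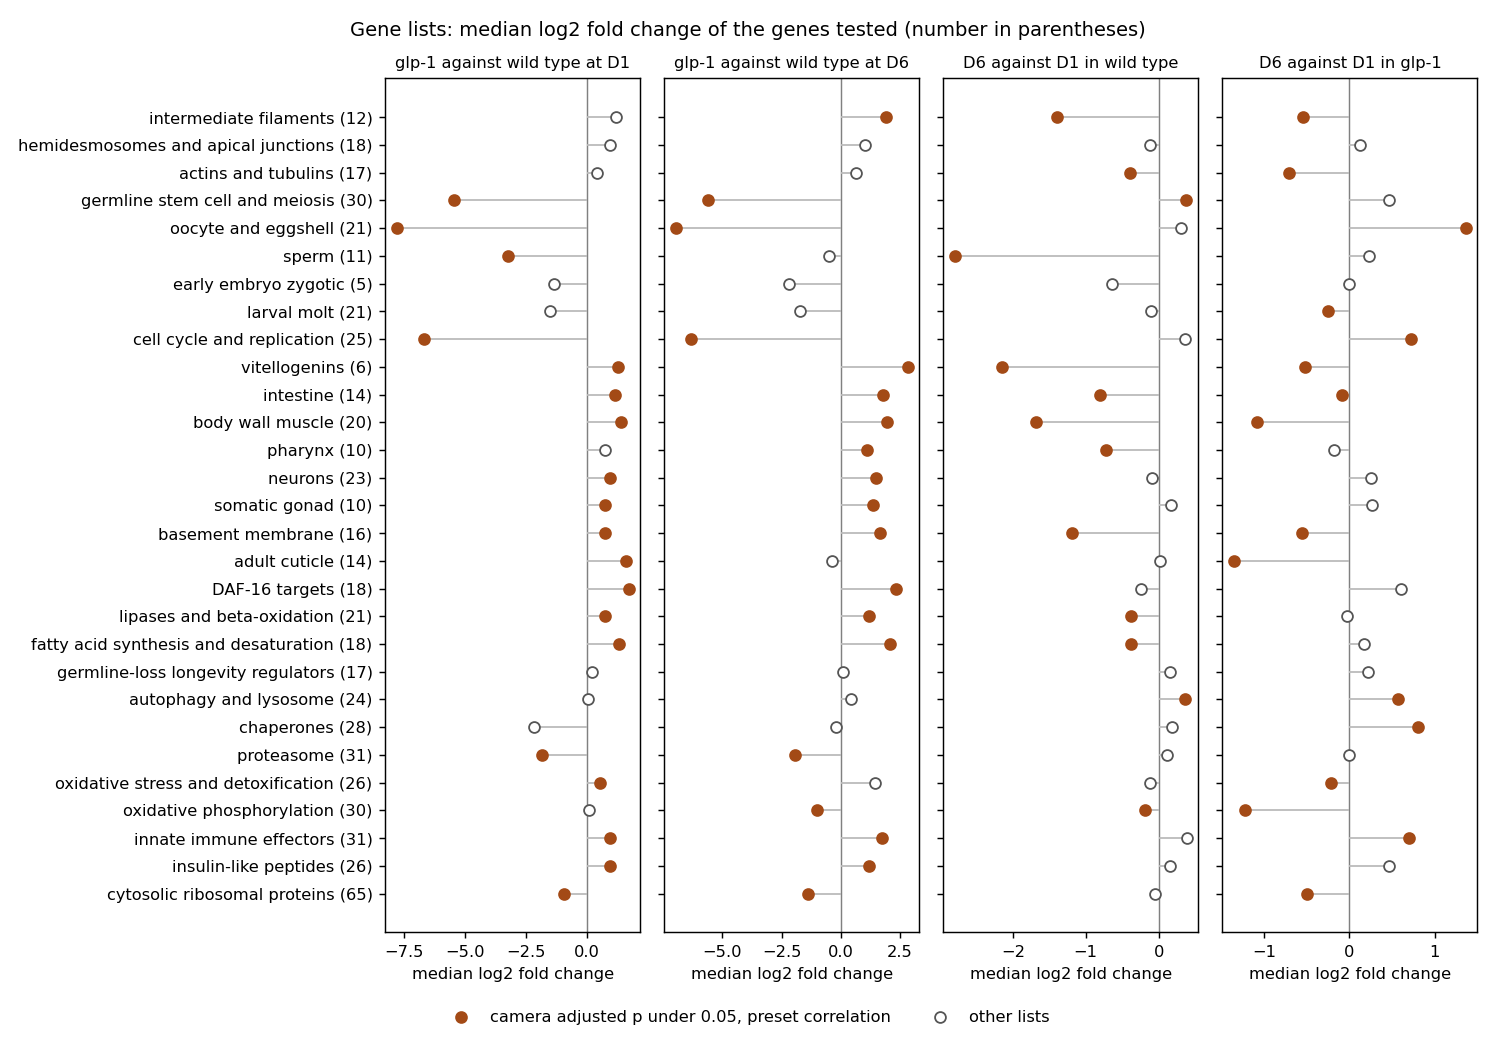
Median log2 fold change of 29 gene lists in 4 comparisons. Each row is a list with its number of tested genes, the horizontal axis of each panel is the median log2 fold change on that panel's own range, and filled points passed camera at a preset correlation. Intermediate filaments have medians of 1.23 and 1.93 against wild type at D1 and D6, and of -1.39 and -0.54 with age in wild type and glp-1.

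In wild type, age from D1 to D6 went together with the shift from 25 °C to a lower temperature. Filament genes fell: 11 of 12 were lower at D6 and 1, lmn-1, was higher (median -1.39; camera adjusted p = 2.28e-06, and adjusted p = 0.175 with an estimated correlation). The falls were -2.55 (SE 0.25) for ifc-1, -2.46 (SE 0.11) for mua-6, -1.75 (SE 0.10) for ifb-2, -1.59 (SE 0.08) for ifa-4, -1.48 (SE 0.06) for ifb-1, -1.44 (SE 0.13) for ifd-1, -1.34 (SE 0.12) for ifc-2, -1.21 (SE 0.15) for ifa-3, -0.86 (SE 0.17) for ifp-1, -0.81 (SE 0.20) for ifd-2 and -0.53 (SE 0.11) for ifa-1. The lamin lmn-1 rose by 0.33 (SE 0.05). Scaled to the muscle and neuron lists, 9 fell and 1 rose, the median was -0.94, and ifa-1 stood at 0.07.

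Muscle, matrix and yolk genes fell in wild type as well. Of 20 muscle genes 17 fell and 2 rose (median -1.68), with the myosin gene unc-54 going from 244 ± 44.8 to 47.9 ± 7.70 FPKM. Of 16 basement membrane genes 14 fell and 1 rose, with the perlecan gene unc-52 at -2.26 (SE 0.10). Of 10 pharynx genes 9 fell, with myo-2 at -0.76 (SE 0.13), of 6 vitellogenin genes 5 fell, with vit-3 at -3.06 (SE 0.10), and of 14 intestinal genes 9 fell and 2 rose, with pho-1 at -2.77 (SE 0.09). All 11 sperm genes fell, with ssp-9 at -4.16 (SE 0.37) and ssq-1 at -3.03 (SE 0.12). Over these 6 lists camera gave adjusted p from 1.02e-08 to 0.00237, and adjusted p from 0.175 to 0.464 with an estimated correlation. Of 23 neuronal genes 4 fell and 3 rose (median -0.0866; adjusted p = 0.454); scaled to the muscle and neuron lists, 15 rose. In that scaling the median was -0.20 for intestine (6 fell, 4 rose) and -0.37 for pharynx (5 fell, 1 rose).

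Metabolic and cytoskeletal lists fell in wild type under FPKM as deposited, while their medians lay above 0 when scaled to the muscle and neuron lists. They were oxidative phosphorylation (16 of 30 fell; gas-1 at -1.11, SE 0.06), fatty acid synthesis (11 of 18 fell, 1 rose; elo-6 at -2.57, SE 0.10), lipases and beta-oxidation (11 of 21 fell, 5 rose; acdh-1 at -3.36, SE 0.16) and actins and tubulins (9 of 17 fell, 2 rose; act-5 at -2.24, SE 0.10). For these 4 lists camera adjusted p ran from 0.000652 to 0.0256, and adjusted p from 0.277 to 0.593 with an estimated correlation. Scaled in that way, camera adjusted p was 0.43, 0.0831, 0.00403 and 0.156 in the same order, and the list calls of all but the lipases ended. Germline stem cell and meiosis genes rose in 16 of 30 (camera adjusted p = 0.00661, and adjusted p = 0.652 with an estimated correlation), with syp-1 at 0.91 (SE 0.11). Autophagy and lysosome genes rose in 16 of 24 and fell in 3 (camera adjusted p = 0.0259, and adjusted p = 0.556 with an estimated correlation), with bec-1 at 0.69 (SE 0.10) and the protease cpl-1 at -1.0 (SE 0.06). In the muscle and neuron scaling all 30 germline genes rose (median 1.01, main 0.38), and 21 autophagy genes rose and 1 fell (median 0.99, main 0.37). Camera then also called the proteasome (31 rose; adjusted p = 0.00115) and ribosomal lists (65 rose; adjusted p = 0.00852) upward, and the adult cuticle list downward (adjusted p = 0.02), although its median was 0.45 with 5 genes rising and 3 falling.

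The rule for named genes ranks only genes with a mean of at least 1 FPKM in each group and no overlap of replicates. Within it the largest rises with age in wild type were thn-1, a thaumatin-like gene, from 1.17 ± 0.642 to 190 ± 33.2 FPKM (6.49, SE 0.19), the lysozyme ilys-3 (5.57, SE 0.73), thn-2 (4.12), asm-3 (3.74) and the antibacterial peptide abf-2 (3.68). The largest falls within it were the collagen genes col-93, from 1724 ± 160 to 24.3 ± 2.71 FPKM (-6.09, SE 0.11), col-20 (-5.60), col-80 (-5.07) and col-160 (-5.06), and grd-3 (-5.50). In the insulin-like list ins-19 rose by 5.04 (SE 0.14) and ins-7 by 1.96 (SE 0.18). Of 31 immune effectors 14 rose and 9 fell, and of 18 DAF-16 targets 6 rose and 6 fell; neither list passed camera (adjusted p = 0.439 and 0.48), and with the muscle and neuron scaling 18 rose and 4 fell, and 7 rose and 2 fell. The DAF-16 list had a median of -0.24 and a mean of 0.41, with mtl-1 rising by 3.58 (SE 0.34). Adjusted over the list alone, the counts were the same for 19 of the 29 lists; for the 65 ribosomal genes, 7 fell and 2 rose over all genes and none passed over the list alone.

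In wild type 7858 genes were called, 4773 higher and 3085 lower at D6, and 1727 changed at least 2-fold (441 higher, 1286 lower). The share of rises was 60.7%, and 84.2% after scaling to the muscle and neuron lists, which moved the median of all genes from 0.13 to 0.69. The 2 reference lists moved apart here (medians -1.68 for muscle and -0.0866 for neurons), so that this scaling carries part of the fall of muscle genes into all genes as a rise.

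In glp-1, age likewise went together with the temperature shift. Of the 12 filament genes 7 fell, 1 rose and 4 did not pass (median -0.54; camera adjusted p = 0.00171, and adjusted p = 0.191 with an estimated correlation). The falls were -4.08 (SE 0.25) for ifc-1, from 32.2 ± 1.73 to 1.01 ± 0.497 FPKM, -1.58 (SE 0.11) for mua-6, -1.1 (SE 0.17) for ifp-1, -0.86 (SE 0.06) for ifb-1, -0.80 (SE 0.13) for ifd-1, -0.72 (SE 0.10) for ifb-2 and -0.36 (SE 0.11) for ifa-1, whose call ended without replicate 2 of glp-1 at D1. The gene ifa-4 does not share this direction and rose by 0.96 (SE 0.08), from 21.2 ± 0.959 to 42.2 ± 1.31 FPKM. Scaled to the muscle and neuron lists, 6 fell and 1 rose (median -0.32). Values for ifc-2 (131 and 132 FPKM), ifd-2 (0.15, SE 0.20), and ifa-3 (0.29, SE 0.15) did not pass, nor did lmn-1, with 50.3 and 50.1 FPKM; ifa-3 passed without replicate 1 of glp-1 at D6 (0.42, adjusted p = 0.045).

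Respiratory chain, ribosomal, cuticle and muscle genes fell with age in glp-1. All 30 genes of oxidative phosphorylation fell (median -1.22; camera adjusted p = 1.29e-31, and adjusted p = 0.142 with an estimated correlation), with F26E4.6, a cytochrome oxidase subunit, from 645 ± 23.4 to 170 ± 13 FPKM, and asg-2 at -1.66 (SE 0.06). Of 65 ribosomal genes 62 fell (median -0.49), with rps-28 at -1.05 (SE 0.13); scaled to the muscle and neuron lists, 34 fell (median -0.27). Of 17 actins and tubulins 13 fell and 2 rose, with act-1 at -1.46 (SE 0.10). Of 20 muscle genes 17 fell (median -1.08), with mup-2 at -2.33 (SE 0.12), of 16 basement membrane genes 10 fell and 3 rose, with unc-52 at -2.01 (SE 0.10), and of 14 adult cuticle genes 8 fell and 2 rose, with col-129 at -5.79 (SE 0.35) and col-119 at -4.88 (SE 0.14). Camera adjusted p for these 5 lists ran from 3.42e-26 to 0.000165, and adjusted p from 0.142 to 0.253 with an estimated correlation.

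Chaperone, autophagy and immune genes rose with age in glp-1. Of 28 chaperone genes 20 rose and 1 fell (camera adjusted p = 2.85e-05, and adjusted p = 0.253 with an estimated correlation), with the endoplasmic reticulum chaperone hsp-4 from 37 ± 2.31 to 324 ± 30.9 FPKM and daf-21 from 66.9 ± 1.48 to 510 ± 22.5 FPKM. Of 24 autophagy and lysosome genes 21 rose (camera adjusted p = 4.8e-05, and adjusted p = 0.191 with an estimated correlation), with atg-16.2 at 1.19 (SE 0.09) and sqst-1 at 1.19 (SE 0.11). Of 31 immune effectors 18 rose and 3 fell (camera adjusted p = 0.0484, and adjusted p = 0.633 with an estimated correlation), with ilys-3 at 6.39 (SE 0.73), lys-10 at 5.26 (SE 0.19) and cnc-2 at 3.44 (SE 0.21). In the detoxification list 9 genes rose and 12 fell, with cyp-14A3 at 7.58 (SE 0.12) and gst-4 at -2.49 (SE 0.24); camera placed it downward (adjusted p = 0.0375, and adjusted p = 0.191 with an estimated correlation) while its mean was 0.08, and its median rose just above 0 when scaled to the muscle and neuron lists.

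Oocyte and cell cycle genes rose with age in glp-1, alongside the uneven germline transcripts of the D6 libraries (1.33%, 0.175% and 0.774% of the wild-type level in replicates 1, 2 and 3). Of 21 oocyte genes 20 rose (median 1.37; camera adjusted p = 0.000905, and adjusted p = 0.633 with an estimated correlation), and of 25 cell cycle genes 16 rose (median 0.73; camera adjusted p = 0.036, and adjusted p = 0.704 with an estimated correlation). The germline stem cell and meiosis list did not pass camera (18 of 30 rose, 1 fell, median 0.47, camera adjusted p = 0.13, and adjusted p = 0.704 with an estimated correlation). With replicate 2 as the one D6 library of glp-1, medians were 0.44 for oocyte, 0.0915 for cell cycle and 0.12 for germline genes, from 1 library. The eggshell gene perm-4 rose from 3207 ± 198 to 6438 ± 407 FPKM. Vitellogenin genes fell in 4 of 6 and rose in 1, with vit-1 at -1.26 (SE 0.13) and vit-5 at 0.76 (SE 0.08), intestinal genes fell in 7 of 14 and rose in 5, and larval molt genes fell in 6 of 21 and rose in 1. Over these 3 lists camera gave adjusted p from 0.00925 to 0.0484, and adjusted p = 0.633 for each with an estimated correlation; the intestinal median, -0.0891, was 0.13 when scaled to the muscle and neuron lists, where the calls of intestine, vitellogenins and cell cycle (camera adjusted p = 0.0564 each) and of immune effectors (0.0519) ended. Among genes within the limits of the naming rule (a mean of at least 1 FPKM in each group, no overlap of replicates), the largest rises were ilys-3, lys-10, thn-1 (5.22), col-183 (5.21) and the neuropeptide gene nlp-39 (5.17), and the largest falls col-93 (-9.49), col-20 (-8.08), col-94 (-8.05), col-92 (-7.30) and col-139 (-6.59). Adjusted over the list alone, the counts were the same for 17 of the 29 lists.

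In glp-1 7444 genes were called, 5318 higher and 2126 lower at D6, and 1915 changed at least 2-fold (1241 higher, 674 lower). The share of rises was 71.4%, and 82.5% after scaling to the muscle and neuron lists, 55.5% after median ratio scaling and 59.3% after trimmed mean scaling; the median of all genes was 0.20, 0.33, 0.07 and 0.09 in that order. In glp-1 as well the muscle and neuron references moved apart (-1.08 and 0.25).

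The interaction asked whether the change with age differed between the genotypes. The D6 animals of both genotypes had also been moved to a lower temperature. A different response to that shift cannot be parted from a different response to age in this contrast. Among filament genes, 8 of 12 had a higher change in glp-1 than in wild type, 2 a lower one, and 2 did not pass. The differences were 2.56 (SE 0.11) for ifa-4, 1.5 (SE 0.22) for ifa-3, 1.34 (SE 0.17) for ifc-2, 1.03 (SE 0.14) for ifb-2, 0.96 (SE 0.28) for ifd-2, 0.87 (SE 0.16) for mua-6, 0.63 (SE 0.19) for ifd-1 and 0.62 (SE 0.09) for ifb-1, and -1.53 (SE 0.36) for ifc-1 and -0.34 (SE 0.07) for lmn-1. The list did not pass camera (adjusted p = 0.0829, and adjusted p = 0.464 with an estimated correlation), and passed when scaled to the muscle and neuron lists (camera adjusted p = 0.0325). In that scaling only 5 genes were higher and 2 lower (median 0.53, main 0.75), and the calls of ifb-1 (0.23), ifd-1 (0.54) and ifd-2 (0.62) ended. As deposited, values for ifa-1 (0.17, SE 0.15) and ifp-1 (-0.24, SE 0.23) did not pass. The gene ifa-3 was of low level in every library, as given above, which leaves little room for a fall in glp-1.

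In the interaction 12 lists passed camera. Respiratory chain genes were more negative in glp-1 in 29 of 30 (median -1.1), with F26E4.6 at -1.90 (SE 0.09) and F29C4.2 at -1.49 (SE 0.11), and ribosomal genes in 58 of 65 (median -0.43), with rpl-39 at -0.98 (SE 0.25) and rps-21 at -0.94 (SE 0.17). The proteasome list was lower (10 of 31 lower, 2 higher), with rpn-11 at -0.61 (SE 0.07) and pbs-1 at -0.56 (SE 0.08), as were adult cuticle (7 of 14 lower, 2 higher), with col-129 at -3.50 (SE 0.50) and dpy-17 at 2.62 (SE 0.30), and actins and tubulins (8 of 17 lower, 3 higher), with tba-1 at -1.46 (SE 0.10) and tba-7 at 1.43 (SE 0.21). Scaled to the muscle and neuron lists, the calls of adult cuticle (camera adjusted p = 0.115) and of actins and tubulins (0.0697) ended. The proteasome then had 20 lower and 0 higher (median -0.53, main -0.12) and all 65 ribosomal genes were lower (median -0.85), and camera also called germline genes downward (17 lower; adjusted p = 0.0157) and immune effectors upward (9 higher, 5 lower; adjusted p = 0.0237). For the 5 lists lower as deposited, camera adjusted p ran from 5.22e-24 to 0.0181, and adjusted p from 0.328 to 0.464 with an estimated correlation. The calls after scaling were not repeated with an estimated correlation.

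Lists with a more positive change in glp-1 were sperm (11 of 11; ssp-11 at 4.38, SE 0.53, and ssq-1 at 2.90, SE 0.17), vitellogenins (6 of 6; vit-3 at 2.12, SE 0.14, and vit-4 at 2.03, SE 0.14), chaperones (16 of 28, with 1 lower; hsp-4 at 3.20, SE 0.10, and daf-21 at 2.89, SE 0.07) and fatty acid synthesis (14 of 18, with 1 lower; dgat-2 at 1.79, SE 0.22, and acs-22 at 1.59, SE 0.11). They also included oocyte genes (11 of 21; cpg-2 at 2.25, SE 0.74, and cpg-1 at 2.08, SE 0.66), for which the uneven D6 libraries apply, basement membrane (11 of 16; mig-6 at 1.41, SE 0.24, and epi-1 at 1.22, SE 0.19) and autophagy and lysosome (17 of 24, with 2 lower; asp-4 at 1.6, SE 0.10, and cpl-1 at 1.54, SE 0.08), whose median of 0.41 became -0.00799 and whose call ended (camera adjusted p = 0.49) when scaled to the muscle and neuron lists. Camera adjusted p for these 7 lists ran from 6.7e-06 to 0.0288, and adjusted p from 0.461 to 0.708 with an estimated correlation. After the same scaling, 0 oocyte genes passed (median 0.43, main 1.13), basement membrane had 6 higher and 2 lower (median 0.42), fatty acid synthesis 6 and 2 (median 0.22) and chaperones 8 and 3 (median 0.17). As deposited, the sperm difference lay mainly in wild type, where all 11 genes fell with age (median -2.79). In glp-1 only 2 of the 11 sperm genes rose (median 0.23) and 9 did not pass. Among genes with a symbol and a mean of at least 1 FPKM in each group, the largest positive differences were msp-31 (4.96), lys-10 (3.68), ugt-25 (3.63), msra-1 (3.55) and skr-12 (3.45), and the largest negative ones col-139 (-4.38), col-12 (-4.29), gst-24 (-3.64), col-3 (-3.62) and col-81 (-3.61). With replicate 2 as the one D6 library of glp-1, cpg-2 stood at 0.74 and cpg-1 at 0.77. In that fit the oocyte median stayed positive at 0.41 (main 1.13). The germline stem cell and meiosis median was -0.33 (main 0.02) and the cell cycle median -0.29 (main 0.29). The call of cpg-2 ended in 9 and that of cpg-1 in 5 of the 12 fits that left out 1 library. Adjusted over the list alone, the counts were the same for 19 of the 29 lists.

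Limma called 6468 genes in the interaction, 4205 positive and 2263 negative, 2347 of them at least 2-fold. The positive share was 65.0%, 31.3% after scaling to the muscle and neuron lists, 47.6% after median ratio scaling and 54.4% after trimmed mean scaling; the median of all genes was 0.15, -0.24, -0.02 and 0.05 in that order. Across all genes tested the changes with age in the 2 genotypes, which share no library, correlated at r = 0.454 (Spearman 0.341). Genes that rose in both numbered 2551, against 1864 for independent lists, and genes that fell in both numbered 1065, against 482. Opposite calls numbered 321 and 554, against 745 and 1205. With the genes of the interaction left out r was 0.787, a set chosen for similar changes.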

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

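The results listed first below are those whose change with age differed between wild type and glp-1 by the interaction term, a test of the difference itself. Age and the shift to a lower temperature cannot be parted in that term either. The 3 patterns after them are changes with age within a genotype. In the interaction the filament and germline lists did not pass camera (adjusted p = 0.0829 and 0.302). Each group had 3 libraries, too few to look for single outlying samples. The splits of the samples were fixed beforehand, but their counts had been seen when the bounds for reading them were written. The reassignment of residuals was added after the splits of the interaction gave 7 of 100, and all tests of the 3 patterns below were chosen after the results were seen. Of these, the comparison of genes of high and low level took the place of a slope fitted over only the genes that had risen (66 of 68 in replicates 1 and 3).

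In the interaction 6468 genes were called by limma. The filament genes were ifa-4 (2.56), ifa-3 (1.5), ifc-2 (1.34), ifb-2 (1.03), ifd-2 (0.96), mua-6 (0.87), ifd-1 (0.63), ifb-1 (0.62), lmn-1 (-0.34) and ifc-1 (-1.53), of which ifd-2, ifd-1 and ifb-1 were not called when scaled to the muscle and neuron lists. Among genes with a symbol and a mean of at least 1 FPKM in each group, the largest differences were msp-31 (4.96), lys-10 (3.68), ugt-25 (3.63), msra-1 (3.55), skr-12 (3.45), col-139 (-4.38), col-12 (-4.29), gst-24 (-3.64), col-3 (-3.62) and col-81 (-3.61). The calls of cpg-2 and cpg-1, named below, ended in 9 and 5 of the 12 fits that left out 1 library. All values are the log2 change with age in glp-1 minus that in wild type.

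Lists with a positive difference had medians of 3.08 for sperm, 1.62 for vitellogenins, 1.13 for oocyte and eggshell, 0.75 for basement membrane, 0.63 for fatty acid synthesis, 0.61 for chaperones and 0.41 for autophagy and lysosome. For sperm the change with age had a median of -2.79 in wild type and 0.23 in glp-1. With the muscle and neuron scaling the medians were 2.80 for sperm, 1.21 for vitellogenins, 0.43 for oocyte (0 of 21 genes called), 0.42 for basement membrane, 0.22 for fatty acid synthesis, 0.17 for chaperones and -0.00799 for autophagy, and with replicate 2 as the one D6 library of glp-1 the oocyte median was 0.41. Negative medians were -1.25 for adult cuticle, -1.1 for oxidative phosphorylation, -0.43 for ribosomal proteins, -0.12 for the proteasome and -0.0935 for actins and tubulins. With the muscle and neuron scaling they were -1.59, -1.51, -0.85, -0.53 and -0.41 in the same order, and the calls of adult cuticle (adjusted p = 0.115) and of actins and tubulins (0.0697) ended. Their members named were ssp-11 (4.38), ssq-1 (2.90), vit-3 (2.12), vit-4 (2.03), cpg-2 (2.25), cpg-1 (2.08), mig-6 (1.41), epi-1 (1.22), dgat-2 (1.79), acs-22 (1.59), hsp-4 (3.20), daf-21 (2.89), asp-4 (1.6), cpl-1 (1.54), col-129 (-3.50), dpy-17 (2.62), F26E4.6 (-1.90), F29C4.2 (-1.49), rpl-39 (-0.98), rps-21 (-0.94), rpn-11 (-0.61), pbs-1 (-0.56), tba-1 (-1.46) and tba-7 (1.43).

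For the 4 comparisons of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05, and the real split was the 1 with the most calls in each. The real and highest other counts were 12167 and 0 for genotype at D1, 12221 and 0 at D6, 7858 and 1 for age in wild type, and 7444 and 1 for age in glp-1. For the interaction, 7 of 100 drawn splits of the libraries within each age gave at least as many genes as the real 6468, with a highest other of 10123, so this count did not exclude chance. Such splits mix the genotypes, and their high counts point to the structure of the samples, since the genotype difference enters the interaction where labels are exchanged at one age. When the fitted genotype and age effects were held and only residuals were reassigned, 1 of 100 splits, the real one, gave as many, and the highest other gave 21.

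The first pattern is the rise of germline-type transcripts from D1 to D6 in glp-1, which camera called for the oocyte and cell cycle lists. The germline stem cell and meiosis list did not pass (camera adjusted p = 0.13). Scaling of the libraries is argued against as the cause of the unevenness between the D6 libraries. Muscle and neuron genes of replicate 1 stood at a median of 0.0881 (log2) over replicate 2, and the 68 germline genes at 2.30. For replicate 3 the values were 0.0179 and 1.65. That comparison holds no D1 library, so it does not test scaling for the rise from D1. Scaled to the muscle and neuron lists, the oocyte and cell cycle medians were 1.26 and 0.68 (as deposited, 1.37 and 0.73). The cell cycle call then ended (camera adjusted p = 0.0564). A small share of RNA from animals with a germline may account for replicates 1 and 3: over all 68 genes, risen or not, the gain as a percent of the wild-type D6 level was 1.06 times as high in the 34 genes of highest as in the 34 of lowest such level in replicate 1 (95% interval 0.857 to 1.39) and 1.01 times in replicate 3 (0.745 to 1.33), near the 1 that a constant share needs. The test decides nothing for replicate 2, whose median gains of 0.0667% and 0.0355% lay near 0. The test speaks only to a constant share of the wild-type profile, and how such RNA came into these libraries was not tested. That includes whether such animals were wild type carried over or mutants with germ cells. A rise in all glp-1 cultures, with age or with the shift to a lower temperature, stays open. Replicate 2 rose by a median of 0.56 (log2), against 2.95 and 2.15 in the others, and 1 library cannot decide it. These values, and the log2 ratios to replicate 2 above, are not on the log2(FPKM + 1) scale of the fold changes. On that scale replicate 2 alone gave list medians of 0.44 for oocyte, 0.0915 for cell cycle and 0.12 for germline genes. The 68 genes were chosen for low levels in glp-1 at D1, which can tilt their rise upward. The labelled D6 temperatures, 20, 21 and 22 °C for replicates 1, 2 and 3, cannot be parted from the differences between these libraries.

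The second pattern is the fall of filament genes with age in wild type. Dilution by germline RNA as the whole cause is argued against, because it lowers every somatic gene alike, while the median of the filament genes minus that of the 23 neuron genes was -1.30 (permutation p = 4e-05), and -0.79 in glp-1 (permutation p = 0.00014). The permutation treats genes as independent, so these p-values can be too small where genes vary together. A fall in wild type was not particular to filament genes, with medians of -1.68 for muscle and -1.185 for basement membrane. Gene length bias is argued against as well, since 0% of 10000 random lists matched on length and level had a median as low (random medians -0.16 to 0.39). Age itself and the temperature shift that goes with it remain open, and the design cannot part them.

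The third pattern is the fall of respiratory chain and ribosomal genes with age in glp-1. A few genes taking more of the library do not explain it, as without the 20 most abundant genes of each library the respiratory chain list had a median of -1.20 (before, -1.22) and the 52 ribosomal genes left of 65 had -0.51 (the same 52 before, -0.52); scaled to the muscle and neuron lists, 34 of 65 ribosomal genes fell (median -0.27). Gene length bias is argued against for the respiratory chain, where 0% of 10000 matched random lists were as low as its 24 members with a length (of 30). For the ribosomal list 0.58% were as low. Age and the lower temperature remain open as untested explanations.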

How the results depend on the processing

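Pseudocounts, trimmed mean scaling and replicate 2 alone were chosen after the data were seen; the other settings were planned. A 2-fold minimum left 1727 genes for age in wild type, 1915 in glp-1 and 2347 for the interaction, and a test against a 1.5-fold change left 1668, 1950 and 1716; both rules ask for more than a change, which lowers the count by construction. The other settings stayed within 1.5 times of the main counts, though the genes called differed in part, as given below. Leaving out 1 library gave 11931 to 11999 genes for genotype at D1, 12052 to 12212 at D6, 6946 to 7530 for age in wild type, 6657 to 7047 in glp-1 and 5990 to 6247 for the interaction, and r between the 2 age changes of 0.441 to 0.460. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.144 and 0.146, over 0.1 in 1 of 18 pairs, and the fit with a replicate block gave 12138, 12218, 7681, 7278 and 6308 genes.

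The correlation of age changes (0.454) was 0.787 without the genes of the interaction, 0.439 scaled to the muscle and neuron lists, 0.441 with no filter, 0.528 at a mean of at least 5 FPKM, 0.402 and 0.512 with pseudocounts of 0.1 and 5, and 0.423 with glp-1 at D6 represented by replicate 2 alone; the cause was not tested. Over all genes, scaling to the muscle and neuron lists kept 80.4% and 82.6% of the calls for genotype at D1 and D6. It kept 81.5% and 87.9% for age in wild type and glp-1, and 68.6% for the interaction. Genes called in the opposite direction numbered 317, 533, 220, 0 and 0 in the same order. For age in glp-1 and the interaction, median ratio scaling kept 77.8% and 83.3% of the calls. Trimmed mean scaling kept 83.1% and 89.6%, and rescaling to the same total 97.8% and 94.8%. In the other comparisons these scalings kept at least 95.4%. Of the 616 named values, mostly picked for large changes, scaling to the muscle and neuron lists ended the calls of 47 and added 5. The values it reversed numbered 13. They were inx-9 (-0.0862), inx-8 (-0.32), tra-1 (-0.50) and ins-17 (-0.14) against wild type at D1, inx-9 (-0.33) and col-119 (-0.69) at D6, and, for age in wild type, ifa-1 (0.0698), tnc-2 (0.0637), tni-4 (0.41), hsp-43 (0.0389), ucr-2.1 (0.0640), rpl-14 (0.29) and rpl-27 (0.33). This scaling shifts every gene of a comparison by nearly the same amount. For age in wild type it also turned camera's direction upward for oxidative phosphorylation (adjusted p = 0.43) and ribosomal proteins (0.00852), and for neurons and somatic gonad (0.83 each), which passed in neither scaling; medians of 10 lists turned upward there. Leaving out 1 library ended 99 and added 10 of the calls of named genes and reversed 0. Fry, which compares a list with no other genes, gave the opposite direction to camera for actins and tubulins at D1 (adjusted p = 0.00856) and D6 (1.9e-06), longevity regulators at D1 (3.59e-05) and D6 (0.0206), autophagy at D1 (0.000136) and oxidative stress with age in glp-1 (0.0119). With an estimated correlation camera called 0 lists in each comparison, against 19, 19, 13, 16 and 12 at the preset one, while fry called 28, 28, 19, 21 and 24. Planned fits with DESeq2 and limma-voom were not run, as they need counts. Without counts, the depth behind single low values is not known.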

Other observations

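Gene families taken by symbol were described after the data had been seen. Among 106 collagen genes (col) 84 were higher and 6 lower in glp-1 at D1, and 37 higher and 18 lower at D6 (median -0.39; adjusted p = 0.17). With age 39 fell and 9 rose in wild type (median 0.07), and 77 fell and 5 rose in glp-1 (median -1.82; camera adjusted p = 1.53e-26, and adjusted p = 0.0671 with an estimated correlation). The change was lower in glp-1 than in wild type for 57 and higher for 11 (adjusted p = 9.06e-10, and adjusted p = 0.181 with an estimated correlation). All 28 major sperm protein genes (msp) were lower in glp-1 at D1 (median -4.62), and all 28 fell with age in wild type (median -3.78; adjusted p = 3.42e-17, and adjusted p = 0.0967 with an estimated correlation). At D6 5 of the 28 were lower in glp-1 and 23 did not pass. With age in glp-1, 0 of the 28 were called (median 0.35).

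Mitochondrial ribosomal protein genes moved with the respiratory chain in glp-1. Of 39 mrpl genes 35 fell with age in glp-1 (median -0.65; adjusted p = 1.24e-16, and adjusted p = 0.0417 with an estimated correlation), and of 27 mrps genes 24 fell and 1 rose (median -0.61; adjusted p = 2.74e-12, and 0.0417 with an estimated correlation). In wild type 12 mrpl and 7 mrps genes rose and none fell. The interaction was negative for 37 of 39 and 25 of 27. Cytochrome P450 genes (cyp) rose in 46 of 60 with age in glp-1 and fell in 4 (adjusted p = 3.58e-08, and adjusted p = 0.0417 with an estimated correlation), with a positive interaction for 43 and a negative one for 2. F-box genes of the fbxb family were lower in glp-1 in 75 of 76 at each age (medians -1.29 and -1.61), nucleoporin genes (npp) in 22 of 22 (medians -3.19 and -3.42), and neuropeptide genes of the flp family were higher in 29 and 30 of 30. Camera adjusted p for these 3 families ran from 4.91e-08 to 2.26e-06, and adjusted p from 0.0417 to 0.0967 with an estimated correlation. None of the medians of these families in these comparisons changed sign under the 4 scalings tried. For the col family at D6 and with age in wild type, the median and the counts of called genes point in opposite directions.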
